A study of Mus musculus with 144 samples.

How the data were processed

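Total RNA of 6 frozen mouse tissues was sequenced in 144 libraries, 48 groups of tissue, age (6 or 24 months), sex and genotype (nmrHAS2 or CreER) with 3 libraries each, grouped by their labels. Per the labels, the RNA was taken up in Trizol, treated with DNase and cleaned on RNeasy columns. The authors trimmed the reads with Trim Galore 0.6.5 and quantified them with Salmon 1.4.0, and the deposited table holds expected counts per gene, which were rounded to whole numbers here. The file has 40946 genes and 0 columns without a sample, and 39779 symbols matched the annotation used here. The genome build and annotation behind the counts are not given in the sources used here, so no positions are printed. The labels do not give the animal behind each library, so p-values measure the spread between these samples, and libraries of several tissues can come from the same animal.

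Each tissue was fitted on its own with edgeR 4.0.16 in R 4.3.3: its 24 libraries with 8 group means, TMM scaling, filterByExpr as the filter on low counts, and the quasi-likelihood F test. Genotype, ageing, the difference in ageing between genotypes and the difference in genotype effect between sexes were contrasts of these means, with both sexes weighted equally. P-values are 2-sided and adjusted by Benjamini and Hochberg within tissue and contrast, with a threshold of 0.05. Standard errors are the log2 change divided by the square root of F. For a count of 0 the limit is 3 counts of the library total, and such limits cover counting error only. Called genes and their recovery were checked on simulated counts with changes of known size.

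For named genes the rule, fixed with the comparisons, tests and gene lists before the data were examined, took per tissue the 4 largest rises and falls between genotypes at 24 months and the 3 largest with age in CreER, among called genes with a mean of at least 2 CPM and the same sign in both sexes. It left out Gm-number and Rik symbols, IDs without a symbol, pseudogenes, immunoglobulin and T cell receptor segments, Xist, Tsix and Y-linked genes. Also named are Has2, genes called in 3 or more tissues with the same sign, up to 4 members with the smallest p of each called list, and the 5 smallest p of each difference between genotypes or sexes. The transgene stands outside this rule and is reported first. Genes whose reads are shared with near-identical copies are given as uncertain.

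In all, 45 gene lists of pathways and cell types were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, correlation 0.01) where at least 5 members were measured, adjusted over 243 tests of list and tissue per comparison. The relation between genotype and ageing was computed across genes and set against a simulation in which the old CreER group is shared and no gene differs.

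Alternatives, whose effect the closing part gives, were size factors by RLE, no filter, DESeq2 1.42.0 in place of edgeR, a replicate block, only the groups compared in the fit, each library left out in turn, and for lists an estimated correlation and fry. Added after seeing the data were library kind as a term, ageing within library kind, and counts without libraries with pancreatic transcripts or with a transgene level against their label, and muscle lists without 1 library. Library kinds were set by the share of counts on 10 RNAs without a poly(A) tail (above or below 1%) and the share of values that are not whole (above or below 40%). Each count was also set against 30 splits of the same libraries, the real one included, or against all 10 where 3 libraries meet 3. No library was left out of the fits, and 0 of 144 pairs of replicates held identical values.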

Results

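RNA was sequenced in 144 libraries of 6 mouse tissues: intestine, kidney, liver, skeletal muscle, spleen and white adipose tissue (WAT). The animals carried a tamoxifen-inducible naked mole-rat hyaluronan synthase 2 transgene (nmrHAS2) or the CreER recombinase alone as control (CreER). They were 6 or 24 months old and of both sexes. Each tissue had 24 libraries in 8 groups of age, sex and genotype, with 3 libraries per group and 6 per genotype and age. Hyaluronan is a large polysaccharide of the extracellular matrix, and the study collected these tissues to ask how nmrHAS2 mice differ from controls as they age. The total count per library was 18 to 109.6 M with a median of 38.15 M.

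The libraries fell into 3 kinds that the labels do not name. In 50 libraries, 10 RNAs that lack a poly(A) tail held 0.000281 to 0.0164% of the counts (the low kind). In 44 libraries these RNAs held 9.61 to 19% and 24.7 to 29.7% of the values above 0 were not whole numbers (the few-fraction kind). In the other 50 they held 8.97 to 23.8% and 48.8 to 68.2% of the values were not whole (the many-fraction kind). Both genotypes had the same kinds in every tissue, age and sex. The ages did not: in intestine, muscle, WAT and female liver most old libraries were of another kind than the young ones of their sex, and males of intestine and WAT had no kind in common between ages. In kidney and spleen each sex had 1 kind at both ages, and all male livers were of the low kind. A value within kind compares only old and young libraries of 1 sex and kind, and was chosen after seeing the data. Per genotype its old side is 1 library in females of intestine, liver, muscle and WAT and in males of muscle, and 3 in males of liver, so the spread behind its p comes largely from other groups.

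Changes are log2 changes ± standard error from edgeR, and adjusted p is adjusted over all genes tested in the tissue unless said otherwise. Levels are CPM, counts scaled to the library total, with their standard deviation over n = 6 libraries per genotype and age, scaled by TMM except for the transgene. A count such as 5 of 6 gives the libraries of the first group that lie on the stated side of the other group's mean log2 CPM in their sex. The mark † means that 1 sex of 1 group was at 0 in all 3 libraries, so that the size of the change is not exact.

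The naked mole-rat transcript was high in muscle, intermediate in intestine and kidney and low in WAT, spleen and liver of nmrHAS2 animals. At 24 months its level in nmrHAS2 against CreER libraries was 175 ± 86.8 against 0.204 ± 0.123 CPM in muscle, 16.8 ± 9.36 against 0.207 ± 0.13 CPM in intestine and 16.1 ± 4.38 against 0.161 ± 0.363 CPM in kidney, each as raw CPM of the library total (n = 6). It was 2.09 ± 1.08 against 0.18 ± 0.125 CPM in WAT, 1.55 ± 1.3 against 0.695 ± 0.594 CPM in spleen and 0.118 ± 0.0867 against 0.00592 ± 0.0145 CPM in liver. At 6 months the levels were 187 ± 130 against 0.318 ± 0.213 CPM in muscle, 8.58 ± 2.81 against 0.179 ± 0.0763 CPM in intestine, 2.94 ± 1.66 against 0.648 ± 0.519 CPM in WAT, 2.69 ± 1.86 against 0.204 ± 0.0964 CPM in spleen and 0.249 ± 0.222 against 0.00622 ± 0.0152 CPM in liver. All 6 young CreER kidneys had a count of 0, which allows up to 0.079 to 0.14 CPM by library (3 counts, counting error only), against 9.48 ± 6.61 CPM in nmrHAS2 kidneys. In old liver 5 of 6 CreER libraries were at 0, and the nmrHAS2 mean lies at the level that a count of 0 allows (0.036 to 0.14 CPM), so no fold is given there.

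The transcript rose with genotype at 24 months in muscle (9.73 ± 0.7, adjusted p = 3.2e-07, 6 of 6), intestine (6.73 ± 0.57, adjusted p = 4.2e-06, 6 of 6) and WAT (3.63 ± 0.42, adjusted p = 0.0011, 6 of 6), and in kidney (adjusted p = 0.000561, 6 of 6), where 4 of 6 CreER libraries were at 0 and no fold is given. In old liver the adjusted p was 0.00373 (6 of 6). In old spleen the difference did not pass (1.02 ± 0.42, 5 of 6, adjusted p = 0.498 over all genes and 0.0254 over the 12 tests of this transcript). The library labelled old female CreER 2 had 1.89 CPM, against 4.09, 1.16 and 1.25 CPM in the nmrHAS2 spleens of its sex and age, and the library labelled old male nmrHAS2 3 had 0.353 CPM, below the male CreER spleens (0.421, 0.529 and 0.617 CPM). At 6 months the transcript rose in muscle (9.12 ± 0.67, adjusted p = 5.29e-07, 6 of 6), intestine (5.38 ± 0.53, adjusted p = 6.39e-05, 6 of 6), spleen (3.44 ± 0.49, adjusted p = 0.0172, 6 of 6) and white adipose tissue (2.49 ± 0.38, adjusted p = 0.0237, 6 of 6) and in kidney (adjusted p = 0.000981, 6 of 6), while liver did not pass (adjusted p = 0.0807, 5 of 6). Mouse Has2, which encodes the animals' own hyaluronan synthase 2, was also higher at 24 months in kidney (5.38 ± 0.51, 6 of 6, adjusted p = 2.49e-05), muscle (4.9 ± 0.52, 6 of 6, adjusted p = 0.000108) and intestine (1.53 ± 0.37, 6 of 6, adjusted p = 0.0225), with adjusted p = 0.596 in spleen (-0.43) and 0.863 in WAT (0.98). At 6 months it rose in kidney (5.16 ± 0.61, 6 of 6, adjusted p = 0.000981) and muscle (4.16 ± 0.5, 6 of 6, adjusted p = 0.000758). The values of the mouse gene are uncertain, since its reads can be shared with the transgene: in nmrHAS2 libraries the median ratio of Has2 to transgene counts was 0.2 in intestine, 0.2 in liver, 0.21 in kidney and 0.23 in muscle, against 0.89 in spleen and 0.72 in WAT.

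**Figure D1:**
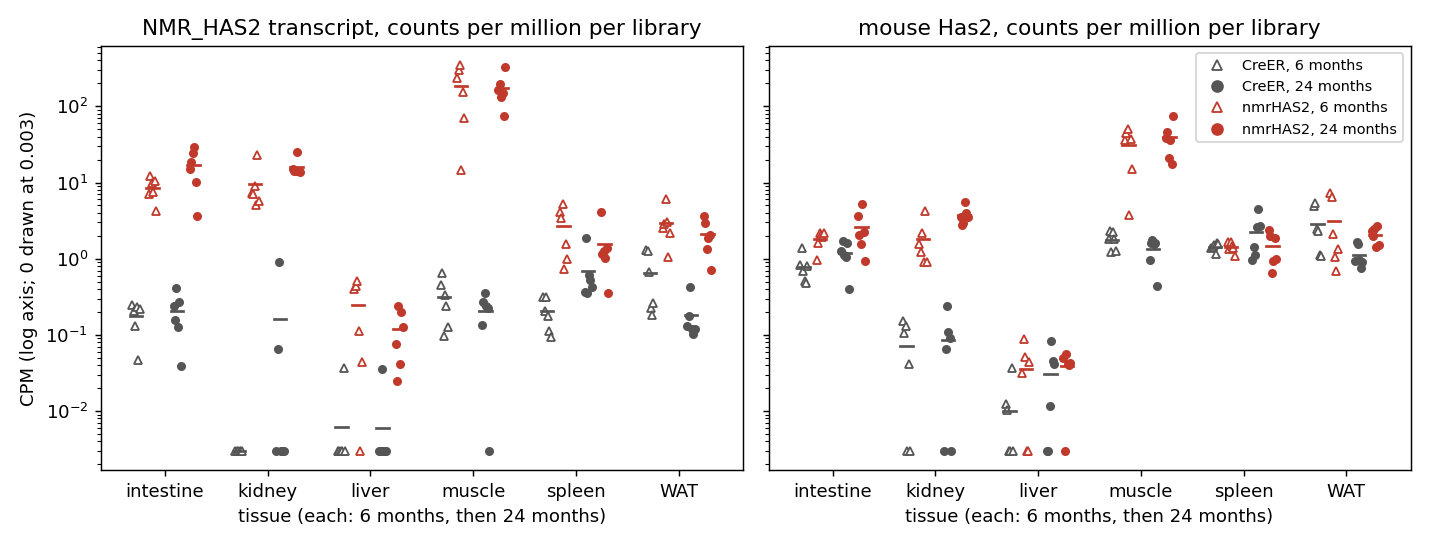
Raw CPM of the naked mole-rat HAS2 transcript and of mouse Has2 on a logarithmic y axis, 1 point per library, by tissue and age; grey is CreER, red nmrHAS2, open triangles 6 months, filled circles 24 months, bars the means of 6 libraries, and values of 0 are drawn at the foot of the axis. Muscle has the highest transgene mean, 175 CPM at 24 months.

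The number of genes that differed between genotypes was far from even across tissues and ages. At 24 months, 3210 rose and 3166 fell in liver of 17270 tested, 683 rose and 348 fell in intestine of 21117, and 231 rose and 96 fell in kidney of 18591. WAT had 33 rises and 1 fall of 21109, muscle 3 and 0 of 18063, and spleen 0 and 1 of 20851. For counts of 0, muscle had 1199 and spleen 1844 genes at an unadjusted p under 0.05 with edgeR, and DESeq2 called 13 and 103 genes. In simulated counts, genes changed by a fold of 2 were called in 51.6 to 75% of cases by tissue. Recovery in real libraries was not tested, and small changes can be missed.

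**Figure D2:**
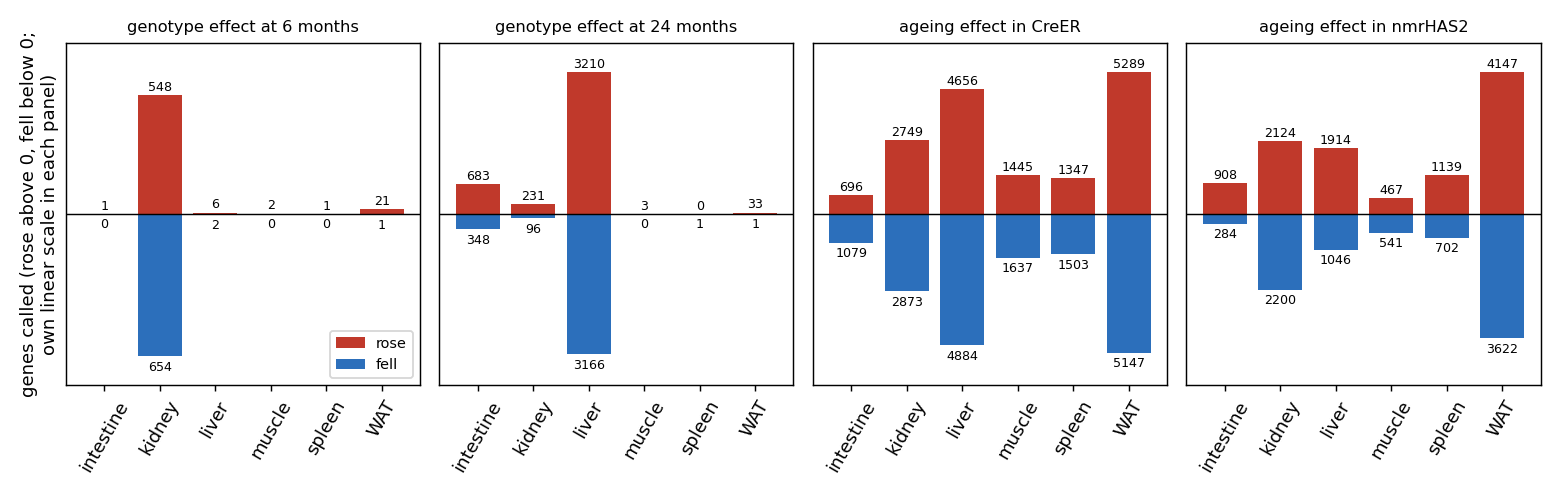
Number of genes called by edgeR in each tissue (x axis), rises above 0 and falls below it (y axis, number of genes, a linear scale of its own in each panel), for 4 comparisons. Liver has the most calls between genotypes at 24 months (3210 rises and 3166 falls), and WAT the most with age in CreER (5289 and 5147).

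The first question is how nmrHAS2 tissues differ from controls in old age. In 24-month livers, genes of macrophages and proliferation were lower in nmrHAS2, and genes of mitochondrial respiration higher (adjusted p = 0.661 with an estimated correlation). Cxcl13, a chemokine that attracts B cells, fell by 5.09 ± 0.65 (6 of 6, adjusted p = 2.35e-05), with 20.9 ± 17.2 against 721 ± 317 CPM. The macrophage receptor Trem2 fell by 2.64 ± 0.35 (6 of 6, adjusted p = 3.06e-05), with 5.7 ± 4.38 against 34 ± 15.5 CPM. The replication factor Mcm3 fell by 1.43 ± 0.15 (6 of 6, adjusted p = 7.92e-06) and the collagen gene Col1a1 fell by 2.07 ± 0.41 (6 of 6, adjusted p = 0.000692). Major urinary protein genes, whose products hepatocytes secrete, had the largest rises: Mup15, at 5680 ± 8340 against 56.1 ± 115 CPM and 0 in the 3 old CreER males (6 of 6, adjusted p = 4.68e-05), Mup17 (7.19 ± 0.99, 6 of 6, adjusted p = 3.64e-05), then Mup9 (5.38 ± 1.08) and Mup1 (5.38 ± 0.95). Mup17 was at 3920 ± 5780 against 25.8 ± 51.5 CPM. These genes are near-identical copies that share reads, so the value of any 1 of them is uncertain. Over the 20 Mup genes measured the median log2 change was 3.45 and 15 were called. Other large falls were Stag3 (-5.4 ± 0.71, 6 of 6, adjusted p = 2.84e-05) and Cd209f (-4.62 ± 1.09, 4 of 6, adjusted p = 0.00247), a meiotic cohesin subunit (-1.7 in females and -9.11 in males) and a lectin receptor whose old male CreER level rests on 1 library (6.84, 0.0294 and 0 CPM), and Lilrb4a†, an inhibitory receptor with near-identical copies (-5.44 ± 1.99, uncertain, adjusted p = 0.0415, 6 of 6).

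Of the gene lists fixed before the data were examined, 21 of the 38 lists tested were called, 9 higher and 12 lower, and the 3 with the smallest p are given here, for intestine and for kidney, and 2 for each other tissue, with erythroid genes added in muscle. Of the 19 macrophage markers, 0 rose, 18 fell and 1 was not called (0 and 18 adjusted over the list alone). Their median was -1.92 (camera adjusted p = 1.83e-12, 0.661 with an estimated correlation). Of the 36 nuclear oxidative phosphorylation genes, 35 rose, 0 fell and 1 was not called (35 and 0 adjusted over the list alone). Their median was 0.43 (camera adjusted p = 3.66e-11, 0.661 with an estimated correlation). Of the 20 cell proliferation genes, 0 rose, 17 fell and 3 were not called (0 and 17 adjusted over the list alone). Their median was -1.37 (camera adjusted p = 3.04e-07, 0.661 with an estimated correlation). Beside these, 13 hepatocyte markers had a median of 0.62 (0.36 to 1.07), and 5 neutrophil genes together were at 8.67 to 83.6 CPM in nmrHAS2 and 24.2 to 665 CPM in CreER. Slco1a1, which male livers express more, rose (3.41 ± 0.62). With DESeq2 the liver had 6679 calls and with 1 library left out 5148 to 6512.

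**Figure D3:**
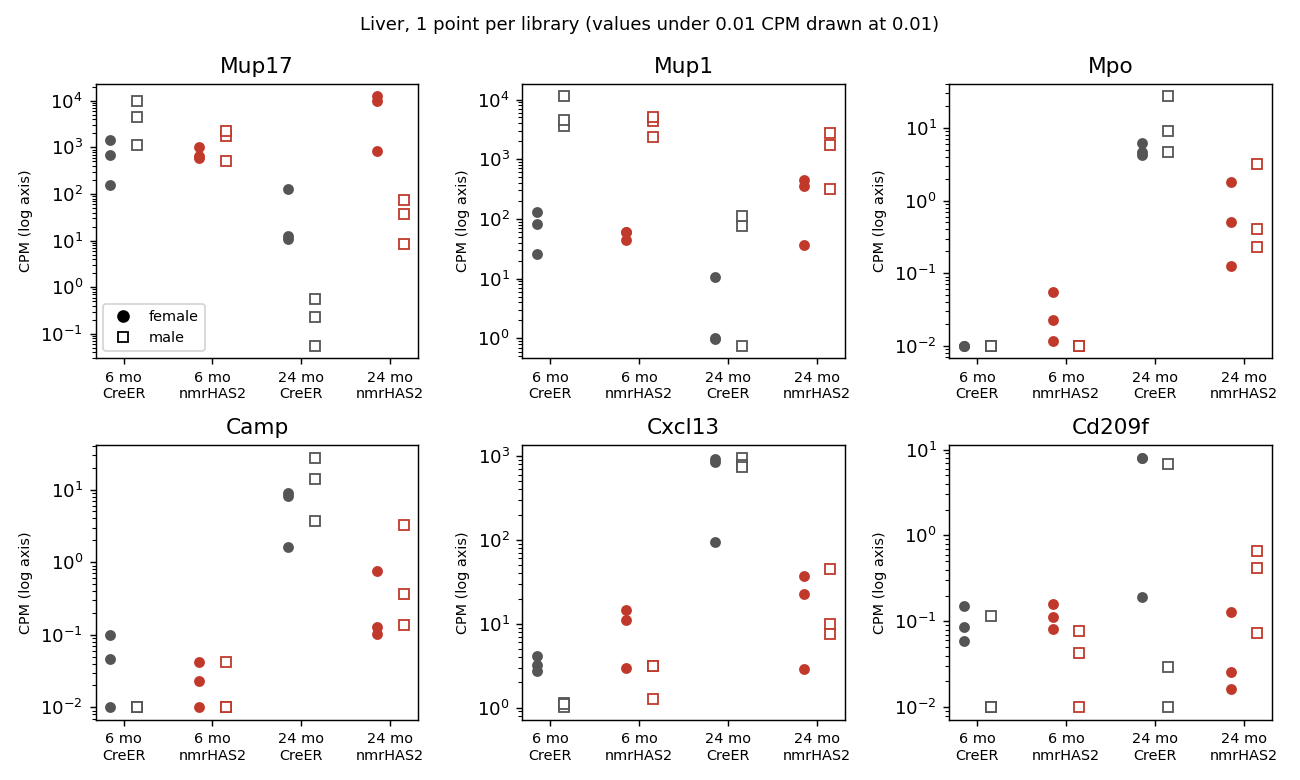
CPM of 6 liver genes on a logarithmic y axis, 1 point per library, by age and genotype (x axis); grey is CreER, red nmrHAS2, filled circles females and open squares males, and values under 0.01 CPM are drawn at 0.01. Cxcl13 averages 721 CPM in old CreER and 20.9 CPM in old nmrHAS2 livers.

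In 24-month intestine, antigen presentation, T cell and Paneth cell genes were lower in nmrHAS2 (adjusted p = 0.661 with an estimated correlation). Plb1, a phospholipase of the intestinal brush border, fell by 5.85 ± 0.6 (6 of 6, adjusted p = 1.77e-05), with 0.355 ± 0.496 against 351 ± 411 CPM. The class II antigen presentation gene H2-Eb1 fell by 0.9 ± 0.18 (6 of 6, adjusted p = 0.00893) and the T cell receptor subunit Cd3g fell by 1.25 ± 0.26 (6 of 6, adjusted p = 0.0111). Defensins of Paneth cells had other large falls, Defa20 (-5.35 ± 0.51), Defa21 (-4.72 ± 0.48) and Defa33 (-5.58 ± 0.87), and are uncertain since near-identical copies share their reads. The largest rises after the transgene were Mptx1, a mucosal pentraxin (6.67 ± 1.82, 4 of 6, adjusted p = 0.0409), the secreted protein Reg2 (4.42 ± 1.26) and the kallikrein Klk1b4 (4.23 ± 0.6), whose reads are shared with copies. Mptx1 was at 249 ± 609 against 0.165 ± 0.125 CPM. In females and males, Plb1 differed by -10.15 and -1.55, Defa20 by -9.85 and -0.86, Defa21 by -9.09 and -0.35, and Defa33 by -10.88 and -0.29. In the same order, Mptx1 differed by 10.82 and 2.51, Reg2 by 6.42 and 2.42, and Klk1b4 by 7.24 and 1.23.

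In intestine 13 of the 44 lists tested were called, 1 higher and 12 lower. Of the 15 antigen presentation genes, 0 rose, 9 fell and 6 were not called (0 and 15 adjusted over the list alone). Their median was -0.86 (camera adjusted p = 1.02e-12, 0.661 with an estimated correlation). Of the 11 Paneth cell and antimicrobial genes, 0 rose, 6 fell and 5 were not called (0 and 9 adjusted over the list alone). Their median was -1.11 (camera adjusted p = 4.47e-08, 0.661 with an estimated correlation). Of the 19 T and NK cell markers, 0 rose, 6 fell and 13 were not called (0 and 12 adjusted over the list alone). Their median was -0.75 (camera adjusted p = 7.02e-08, 0.661 with an estimated correlation). The old female CreER libraries 1 to 3 had 31500, 41100 and 48200 CPM of defensins, levels that stood apart from the other intestines. They had 0.523, 5260 and 4070 CPM of 6 pancreatic transcripts. Leaving out 1 library moved the total of 1031 by over 1.5 times for old female CreER 1 and 2 (631, 473), old female nmrHAS2 1 and 3 (2018, 658), old male CreER 1 and 2 (684, 423) and old male nmrHAS2 1 (383). It was 1788 with DESeq2 and 160 with only the 24-month libraries fitted.

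In 24-month kidney, few members passed of the lists that camera called, those of immediate early and stress response genes higher in nmrHAS2 and of ribosomal protein genes lower (adjusted p = 0.661, 0.668 and 0.667 with an estimated correlation). Havcr1, a receptor that injured proximal tubule cells display, rose by 2.66 ± 0.6 (4 of 6, adjusted p = 0.0285), with 32.7 ± 40.7 against 3.8 ± 2.25 CPM. The fatty acid hydroxylase Cyp4a14 fell by 1.8 ± 0.42 (6 of 6, adjusted p = 0.0377). The matricellular protein Ccn1 rose by 0.97 ± 0.13 (6 of 6, adjusted p = 0.00194) and the endocytic receptor Cubn of the proximal tubule rose by 0.45 ± 0.09 (6 of 6, adjusted p = 0.0211). Further large rises were in the cation channel Trpc4 (1.92 ± 0.45) and the protease inhibitor A2m (1.76 ± 0.44), and further falls in the lipocalin Apod (-1.54 ± 0.27) and the macrophage scavenger receptor Msr1 (-1.37 ± 0.31).

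In kidney 17 of the 40 lists tested were called, 6 higher and 11 lower. Of the 26 cytosolic ribosomal protein genes, 0 rose, 0 fell and 26 were not called (0 and 21 adjusted over the list alone). Their median was -0.17 (camera adjusted p = 6.19e-11, 0.667 with an estimated correlation). Of the 17 immediate early genes, 2 rose, 0 fell and 15 were not called (11 and 0 adjusted over the list alone). Their median was 0.64 (camera adjusted p = 6e-07, 0.661 with an estimated correlation). Of the 18 unfolded protein and integrated stress response genes, 1 rose, 0 fell and 17 were not called (5 and 0 adjusted over the list alone). Their median was 0.37 (camera adjusted p = 1.89e-05, 0.668 with an estimated correlation). The 327 calls moved by over 1.5 times without 1 library: old female CreER 1 and 3 (181, 85), old female nmrHAS2 1, 2 and 3 (45, 646, 132), old male CreER 2 (179) and old male nmrHAS2 1, 2 and 3 (1441, 108, 29). DESeq2 called 930 genes, and 3 were called with only the 24-month libraries fitted.

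In 24-month muscle the genes that passed were the transgene, Has2 and 2310015K22Rik, a gene of unknown function that falls outside the naming rule and was chosen after its values were seen: 2310015K22Rik (1.48 ± 0.23, 6 of 6, adjusted p = 0.0257), at 1.56 ± 0.824 against 0.526 ± 0.193 CPM. As groups, genes of mitochondrial respiration were higher in nmrHAS2 and genes of macrophages lower (adjusted p = 0.661 with an estimated correlation). Of the 36 nuclear oxidative phosphorylation genes, 0 rose, 0 fell and 36 were not called (0 and 0 adjusted over the list alone). Their median was 0.27 (camera adjusted p = 8.03e-14, 0.661 with an estimated correlation). Of the 19 macrophage markers, 0 rose, 0 fell and 19 were not called (0 and 0 adjusted over the list alone). Their median was -0.71 (camera adjusted p = 1.01e-07, 0.661 with an estimated correlation). Of the 12 erythroid markers, 0 rose, 0 fell and 12 were not called (0 and 11 adjusted over the list alone). Their median was -2.36 (camera adjusted p = 0.000315, 0.668 with an estimated correlation). In muscle 18 of the 40 lists tested were called, 8 higher and 10 lower, and 0 of these held with fry. The library old male CreER 3 stood apart, with 5120 CPM of 5 neutrophil genes and 18 M counts. Without it 6 of the 18 lists held, and the medians were 0.3 (adjusted p = 1.11e-15) for respiration, -0.38 (adjusted p = 0.00278) for macrophages and -0.29 (adjusted p = 0.736) for erythroid genes.

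In 24-month spleen 1 gene fell, Gm14139, chosen after its values were seen since the naming rule leaves such symbols out: Gm14139 (-2.44 ± 0.37, 6 of 6, adjusted p = 0.0418), at 0.175 ± 0.0989 against 1.27 ± 1.08 CPM. As groups, cholesterol synthesis and ribosomal protein genes were lower in nmrHAS2, with small medians (adjusted p = 0.661 and 0.722 with an estimated correlation). Of the 21 cholesterol synthesis genes, 0 rose, 0 fell and 21 were not called (0 and 3 adjusted over the list alone). Their median was -0.15 (camera adjusted p = 2.89e-06, 0.661 with an estimated correlation). Of the 26 cytosolic ribosomal protein genes, 0 rose, 0 fell and 26 were not called (0 and 0 adjusted over the list alone). Their median was -0.17 (camera adjusted p = 1.14e-05, 0.722 with an estimated correlation). In spleen 12 of the 39 lists tested were called, 3 higher and 9 lower. Without the libraries labelled old female CreER 2 and old male nmrHAS2 3 the count was 0. Leaving out 1 library moved it by over 1.5 times for old female CreER 1, 2 and 3 (0, 0, 0), old female nmrHAS2 1, 2 and 3 (0, 93, 0), old male CreER 1, 2 and 3 (0, 45, 0) and old male nmrHAS2 1, 2 and 3 (3, 3, 0).

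In 24-month WAT, transcripts of digestive enzymes made in the pancreas were higher in nmrHAS2 (adjusted p = 0.305 with an estimated correlation). The proteases and lipases Cela2a† (13.63 ± 2.32, 5 of 6, adjusted p = 0.0173) and Pnlip† (13.26 ± 2.16, 6 of 6, adjusted p = 0.012), Cel† (12.92 ± 2.14) and the amylase gene Amy2a1† (12.9 ± 2.36, uncertain since copies share its reads, 5 of 6, adjusted p = 0.0458) had the largest rises. Pnlip was at 931 ± 1200 against 0.999 ± 1.75 CPM. The 1 fall was Nfkbiz, a nuclear regulator of NF-kB, which fell by 0.63 ± 0.12 (6 of 6, adjusted p = 0.0316), with 26.1 ± 5.68 against 40.8 ± 10.9 CPM, and the clock gene Per3 rose by 0.93 ± 0.15 (5 of 6, adjusted p = 0.00879). Of the 12 pancreatic acinar markers, 12 rose, 0 fell and 0 were not called (12 and 0 adjusted over the list alone). Their median was 12.18 (camera adjusted p = 3.23e-34, 0.305 with an estimated correlation). Of the 36 nuclear oxidative phosphorylation genes, 0 rose, 0 fell and 36 were not called (0 and 0 adjusted over the list alone). Their median was 0.14 (camera adjusted p = 2.89e-06, 0.722 with an estimated correlation). In WAT 18 of the 42 lists tested were called, 9 higher and 9 lower. The pancreatic transcripts came from few libraries, since 6 pancreatic genes together reached 0.303, 120, 149, 3580, 7260 and 10200 CPM in the 6 old nmrHAS2 libraries. Without libraries at or above 1000 CPM of these genes the count was 7, and it was 0 with only the 24-month libraries fitted and 114 with DESeq2. Leaving out 1 library moved it by over 1.5 times for old female CreER 1, 2 and 3 (2, 1, 1) and old male CreER 1, 2 and 3 (1, 17, 1).

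The genes that make, bind and break down hyaluronan were not called as a list in any of the 6 tissues at 24 months. Their median log2 change was -0.05 in intestine (adjusted p = 0.483, 1 rose and 1 fell of 19, 1 and 1 adjusted over the list alone), -0.06 in kidney (adjusted p = 0.423, 1 rose and 1 fell of 16, 3 and 1 adjusted over the list alone) and -0.18 in liver (adjusted p = 0.525, 3 rose and 4 fell of 13, 3 and 4 adjusted over the list alone). It was -0.07 in muscle (adjusted p = 0.9, 1 rose and 0 fell of 18, 1 and 0 adjusted over the list alone), 0.18 in spleen (adjusted p = 0.316, 0 rose and 0 fell of 19, 1 and 0 adjusted over the list alone) and 0.03 in WAT (adjusted p = 0.644, 0 rose and 0 fell of 20, 0 and 0 adjusted over the list alone). In kidney the median (-0.06) and the mean (0.35) differed in sign, and the test pointed up. In muscle the median (-0.07) and the mean (0.09) differed too, and the test pointed down. Has2 itself is a member. In all, 99 of 243 list tests were called at 24 months, 36 higher and 63 lower, and 0 of these held with an estimated correlation in place of the preset 0.01 and 22 with fry. Another split of the libraries called 86.

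A small set of genes differed in the same direction in 3 or more tissues at 24 months. Lower in intestine, kidney and liver were Srgn, a proteoglycan of immune cell granules, P2ry13, a purine receptor, Gimap6, a lymphocyte GTPase, the phospholipase Plaat3 and the interferon-induced GTPase Gbp2b. Srgn had -0.53 in intestine, -0.35 in kidney and -1.52 in liver, P2ry13 -0.63, -1.24 and -1.77, Gimap6 -0.61, -0.29 and -0.58, Plaat3 -0.62, -0.59 and -1.01 and Gbp2b -0.82, -1.14 and -1.92 in the same order. Higher in the same tissues were the lysosomal sulfatase Arsb, which removes sulfate from glycosaminoglycans (0.56, 0.71 and 0.38), the adhesion protein Igsf11 (1.7, 0.5 and 0.58) and the autophagy protein Trp53inp2 (0.84, 0.39 and 1.16), beside Has2 in 3 tissues and the transgene in 5. Each call outside these 2 had an adjusted p between 2.59e-05 and 0.0444 in its tissue, with at least 4 of 6 libraries on the same side. In intestine, where the old female CreER libraries stand apart, females and males had Arsb 1.23 and -0.1, Plaat3 -1.08 and -0.15, Trp53inp2 1.47 and 0.21, Gbp2b -1.37 and -0.27, and Igsf11 2.96 and 0.44. In 2 or more tissues 218 genes rose and 162 fell, where 1000 random draws of as many calls gave a mean of 148 (at most 181) and 66.9 (at most 87). In 3 or more, 5 rose and 5 fell, against random means of 1.4 (at most 6) and 0.3 (at most 4). Tissues can come from the same animals, so no test across tissues was made.

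At 6 months the question is what differs before old age. Kidney had the most calls. Genes of the 6-month comparison and of ageing in nmrHAS2 were ranked by the same rule after the values were seen. Igha, the constant region of mucosal antibodies, rose by 1.44 ± 0.39 (4 of 6, adjusted p = 0.0328), and Jchain, which joins antibody units, rose by 1.38 ± 0.33 (4 of 6, adjusted p = 0.0182), with 35.3 ± 26.8 against 10.9 ± 2.81 CPM. The clock output genes Dbp (-1.39 ± 0.3, 6 of 6, adjusted p = 0.0126) and Ciart (-1.55 ± 0.37, 6 of 6, adjusted p = 0.0188), the glucuronosyltransferase Ugt1a2 (-1.5 ± 0.34) and the protocadherin Pcdhgc4 (-2.42 ± 0.52) had the largest falls. Dbp was at 19.1 ± 17.6 against 50.6 ± 39.5 CPM. In kidney 548 rose and 654 fell of 18591, with 661 calls in all without a filter on low counts, 1899 with only the 6-month libraries fitted and 1869 with DESeq2. Left-out libraries moved the total of 1202 by over 1.5 times for young female CreER 1 and 2 (620, 410), young female nmrHAS2 1, 2 and 3 (658, 568, 732), young male CreER 3 (650) and young male nmrHAS2 2 and 3 (662, 730).

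In 6-month WAT the rises were led by genes of skeletal muscle, among them Ckm (5.77 ± 0.97, 6 of 6, adjusted p = 0.0241) and Tnnt3 (4.93 ± 0.82, 6 of 6, adjusted p = 0.0241). Genes of skeletal muscle together were at 140, 70.9, 517, 154, 11.7 and 196 CPM in the 6 nmrHAS2 libraries and at 17.4 to 53.7 CPM in CreER. The 1 fall, chosen after its values were seen, was AU015791 (-5.23 ± 0.97, 6 of 6, adjusted p = 0.0411). In liver the 6 rises and 2 falls, chosen after their values were seen, were Map4k4 (0.86 ± 0.13), Specc1l (0.43 ± 0.07), Ptprb (0.57 ± 0.09), Hecw2 (0.8 ± 0.13), Rnf144a (1.01 ± 0.18) and Adamts4 (2.28 ± 0.4), then Per2 (-1.34 ± 0.24) and Zfp967 (-0.64 ± 0.11), each in 6 of 6 libraries and with adjusted p from 0.028 to 0.0485. Per2 is a core repressor of the circadian clock. In liver DESeq2 called 496 genes, and 0 passed with only the 6-month libraries fitted. The transgene was the 1 gene called in intestine and in spleen, and with Has2 the 2 genes called in muscle. Falls numbered 0 in intestine, muscle and spleen by edgeR, where 556, 1017 and 2661 genes had an unadjusted p under 0.05 and DESeq2 called 2, 46 and 73 genes in all. In WAT 21 rose and 1 fell, while DESeq2 called 88 and 1328 had an unadjusted p under 0.05. The count was 0 with a replicate block and with only the 6-month libraries fitted. It was also 0 without 3 old nmrHAS2 libraries, which are outside this comparison. Left out in WAT, single libraries moved the total by over 1.5 times for young female CreER 1, 2 and 3 (0, 1, 0), young female nmrHAS2 2 and 3 (35, 0), young male CreER 1, 2 and 3 (2, 0, 0) and young male nmrHAS2 1 and 3 (8, 0). In liver it did so for young female CreER 1 and 2 (0, 0), young female nmrHAS2 1 and 3 (0, 17), young male CreER 1, 2 and 3 (152, 0, 1) and young male nmrHAS2 1, 2 and 3 (808, 41, 3), and in spleen for young female CreER 1, 2 and 3 (0, 0, 0), young female nmrHAS2 3 (0), young male CreER 1, 2 and 3 (0, 6, 0) and young male nmrHAS2 1, 2 and 3 (4, 5, 0).

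Ageing in the CreER controls gives the changes against which the genotype differences are set. In old CreER livers, genes of mitochondrial respiration were lower and genes of p53 response and senescence higher than at 6 months (adjusted p = 0.289 and 0.0381 with an estimated correlation). Mpo, the myeloperoxidase of neutrophils, was at 9.34 ± 8.98 CPM at 24 months and at 0 in all 6 young libraries (adjusted p = 3.23e-06, 6 of 6). The antimicrobial peptide gene Camp† rose by 9.7 ± 1.17 (6 of 6, adjusted p = 1.47e-06, 9.96 within kind). The largest falls were in Mup genes, uncertain one by one since copies share their reads: Mup15, at 56.1 ± 115 against 4440 ± 5400 CPM (adjusted p = 1.33e-06), Mup17 (-9.02 ± 1.06, 6 of 6, adjusted p = 5.77e-07, -10.03 within kind), and Mup22, at 372 ± 911 against 12400 ± 7490 CPM (adjusted p = 0.0136, 0.0579 within kind) with 5 of 6 old libraries at 0. Slco1a1, a male-biased transporter, fell by 6.85 ± 0.48 (6 of 6, adjusted p = 3.01e-09, -6.7 within kind), and Trem2 rose by 6.3 ± 0.45 (6 of 6, adjusted p = 3.08e-09, 6.3 within kind), with 34 ± 15.5 against 0.483 ± 0.275 CPM. Among the 36 nuclear oxidative phosphorylation genes, 0 rose, 36 fell and 0 were not called (0 and 36 adjusted over the list alone). Their median was -0.88 (camera adjusted p = 1.98e-15, 1.28e-16 within kind, 0.289 with an estimated correlation). Among the 16 p53 target and senescence genes, 13 rose, 0 fell and 3 were not called (13 and 0 adjusted over the list alone). Their median was 1.13 (camera adjusted p = 0.000183, 0.000271 within kind, 0.0381 with an estimated correlation). Beside these, 13 hepatocyte markers had a median of -0.78 (-1.54 to 0.41), and 5 neutrophil genes were at 24.2 to 665 CPM in old and 0.448 to 4.62 CPM in young livers. In all, 4656 rose and 4884 fell of 17270 genes, and 8181 were called within kind.

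In old CreER kidneys, genes of macrophages, p53 response and antibody-producing cells were higher than at 6 months (adjusted p = 0.289, 0.0381 and 0.0466 with an estimated correlation). Cxcl13 rose by 3.83 ± 0.64 (6 of 6, adjusted p = 0.000159), with 12 ± 8.94 against 0.922 ± 0.69 CPM, and the antibody gene Ighg2c rose by 4.07 ± 0.79 (5 of 6, adjusted p = 0.000629). The phosphate transporter Slc34a1 fell by 1.09 ± 0.11 (6 of 6, adjusted p = 2.42e-06). Other large changes were in muscle genes, Myh1 (3.9 ± 0.87), Myl2 (-5.8 ± 1.76) and Myh6 (-5.63 ± 1.27), and in Mup7† (-6.62 ± 2.04, uncertain, 5 of 6, adjusted p = 0.0194). The library old male CreER 2 had 731 CPM of skeletal muscle genes. Among the 18 macrophage markers, 16 rose, 0 fell and 2 were not called (17 and 0 adjusted over the list alone). Their median was 1.73 (camera adjusted p = 4.86e-13, 0.289 with an estimated correlation). Among the 15 p53 target and senescence genes, 10 rose, 0 fell and 5 were not called (11 and 0 adjusted over the list alone). Their median was 0.47 (camera adjusted p = 2.94e-06, 0.0381 with an estimated correlation). Among the 13 plasma cell markers, 9 rose, 0 fell and 4 were not called (10 and 0 adjusted over the list alone). Their median was 2.46 (camera adjusted p = 1.28e-05, 0.0466 with an estimated correlation). In all, 2749 rose and 2873 fell of 18591 genes.

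In old CreER spleens, macrophage, p53 response and hyaluronan genes were higher than at 6 months (adjusted p = 0.267, 0.0381 and 0.126 with an estimated correlation). Lef1, a transcription factor of naive T cells, fell by 2.84 ± 0.31 (6 of 6, adjusted p = 4.21e-05), with 3.64 ± 1.08 against 27.3 ± 11.6 CPM. Dapl1 (-4.55 ± 0.61) and the nucleoside transporter Slc28a2b (-3.7 ± 0.46) were the other largest falls, and Gpat2 (6.41 ± 1.4) of lipid synthesis and the dehydrogenase Aldh8a1 (4.78 ± 1.31) the largest rises. The complement receptor Cr2 of B cells fell by 2.73 ± 0.38 (6 of 6, adjusted p = 0.000268). Among the 18 macrophage markers, 14 rose, 0 fell and 4 were not called (17 and 0 adjusted over the list alone). Their median was 1.14 (camera adjusted p = 8.01e-13, 0.267 with an estimated correlation). Among the 16 p53 target and senescence genes, 6 rose, 0 fell and 10 were not called (7 and 0 adjusted over the list alone). Their median was 0.39 (camera adjusted p = 3.53e-05, 0.0381 with an estimated correlation). The integrin subunit Itgam (1.86 ± 0.29) rose, and 5 neutrophil genes were at 1290 to 5530 CPM in old and 208 to 806 CPM in young spleens. The pancreatic transcripts Cpa1 and Pnliprp1 were at 0 in the 3 old males, and in 1 and 0 young libraries. Pancreatic content may thus differ with age too. The hyaluronan genes were called higher (median 0.29, adjusted p = 0.00482, adjusted p = 0.126 with an estimated correlation), where 2 of 19 rose, Vcan (2.2 ± 0.37) and Cemip2 (0.29 ± 0.1), 0 fell and 17 were not called, and 1 rose adjusted over the list alone. In all, 1347 rose and 1503 fell of 20851 genes (71 calls in females and 2423 in males, a difference not tested), which left-out libraries moved by over 1.5 times: old female CreER 3 (1827), old male CreER 2 and 3 (4691, 1777) and young male CreER 3 (1881).

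In old CreER muscle, genes of mitochondrial respiration were lower than at 6 months (adjusted p = 0.528 with an estimated correlation). The water channel Aqp4 of fast fibres fell by 2.34 ± 0.3 (6 of 6, adjusted p = 0.000418, -2.31 within kind), with 5.51 ± 2.06 against 31.7 ± 18.2 CPM, and Nrep, a neuronal regeneration related protein, fell by 2.52 ± 0.34 (6 of 6, adjusted p = 0.000689, -2.2 within kind). The lectin Chil3 rose by 6.86 ± 1.2 (6 of 6, adjusted p = 0.00267, 7.75 within kind), with 18.8 ± 44 against 0.0504 ± 0.0277 CPM, and by 3.63 without the library old male CreER 3, which had 5120 CPM of 5 neutrophil genes. The gene Gadd45a, a stress gene of denervated muscle, rose by 1.76 ± 0.24 (6 of 6, adjusted p = 0.000748, 1.88 within kind). The 7S RNA gene Rn7s6 and the 5S ribosomal RNA gene n-R5s193, which lack a poly(A) tail, had the largest pooled rises, which turned within kind: Rn7s6† (11.01 ± 2.79, 4 of 6, adjusted p = 0.0173, -0.4 within kind at adjusted p = 1) and n-R5s193 (8.21 ± 1.72, 5 of 6, adjusted p = 0.0061, -0.64 within kind at adjusted p = 0.602). Among the 36 nuclear oxidative phosphorylation genes, 0 rose, 19 fell and 17 were not called (0 and 27 adjusted over the list alone). Their median was -0.43 (camera adjusted p = 1.71e-10, 0.528 with an estimated correlation). The hepatocyte transcript Alb (2.75 ± 0.76, 2.19 within kind at adjusted p = 0.283) moved with female libraries of 24 months, which held 115 to 395 CPM of hepatic genes. In all, 1445 rose and 1637 fell of 18063, with 3172 called within kind, where the old side is 1 female and that male, and 1608 with library kind as a term. Leaving out 1 library moved the total of 3082 by over 1.5 times for old female CreER 2 and 3 (1570, 1861), old male CreER 3 (5728), young female CreER 1 (1494) and young male CreER 3 (1563).

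In old CreER intestine, adipocyte and keratinocyte transcripts were higher than at 6 months (adjusted p = 0.392 and 0.0381 with an estimated correlation). The lipid carrier Fabp4 of adipocytes rose by 2.74 ± 0.4 (6 of 6, adjusted p = 0.000923, 5.33 within kind), with 123 ± 159 against 10.1 ± 3.15 CPM, the integrin Itgam of myeloid cells rose by 0.87 ± 0.11 (6 of 6, adjusted p = 0.000331, 1.01 within kind), and Plb1 rose by 5.99 ± 0.58 (4 of 6, adjusted p = 1.96e-05, 11.24 within kind). Rn7s6 and n-R5s193 again had large pooled rises with small values within kind, Rn7s6 (9.33 ± 1.36, 6 of 6, adjusted p = 0.000895, 0.6 within kind at adjusted p = 0.791) and n-R5s193 (8.52 ± 1.26, 6 of 6, adjusted p = 0.000923, 1.1 within kind at adjusted p = 0.812). The largest falls, Rps27rt† (-8.85 ± 2.2, 6 of 6, adjusted p = 0.0234, -1.76 within kind at adjusted p = 0.469), Srp54b† (-7.8 ± 2.33, 5 of 6, adjusted p = 0.0493, 0.15 within kind at adjusted p = 0.781) and Tmem254c† (-7.11 ± 2.03, 6 of 6, adjusted p = 0.0422, -0.39 within kind at adjusted p = 0.562), are genes with near-identical copies and are uncertain. Srp54b turned within kind. Among the 13 adipocyte markers, 8 rose, 0 fell and 5 were not called (9 and 0 adjusted over the list alone). Their median was 2.51 (camera adjusted p = 4.1e-06, 0.392 with an estimated correlation). Among the 6 keratinocyte and mammary epithelial markers, 3 rose, 0 fell and 3 were not called (4 and 0 adjusted over the list alone). Their median was 1.09 (camera adjusted p = 0.000176, 0.0381 with an estimated correlation). In all, 696 rose and 1079 fell of 21117, with 486 called within kind and 22 with library kind as a term. By sex, 4498 genes were called in females and 0 in males (1353 with an unadjusted p under 0.05, 181 with DESeq2), and Plb1 had 11.4 and 0.58. The old females are the 3 libraries that stand apart, and 7 genes of the distal intestine had a median of 2.98 in them against young females. Left-out libraries moved the total of 1775 by over 1.5 times for old female CreER 1 and 2 (1116, 770), old male CreER 2 (948), young female CreER 1 (1027) and young male CreER 1 and 2 (1133, 1133).

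In old CreER WAT, genes of cholesterol synthesis were lower than at 6 months (adjusted p = 0.485 with an estimated correlation). Dgat2 of triglyceride synthesis fell by 3.65 ± 0.58 (6 of 6, adjusted p = 7.01e-05, -3.61 within kind at adjusted p = 0.0591), with 123 ± 45.5 against 1550 ± 662 CPM. The B cell gene Cd22 rose by 3.1 ± 0.59 (6 of 6, adjusted p = 0.000356, 4.41 within kind). The largest rises were histone genes, whose mRNAs lack a poly(A) tail and share reads, Hist1h2ap† (7.28 ± 0.91, 6 of 6, adjusted p = 1.2e-05, 1.74 within kind at adjusted p = 0.246) and H2ac11† (6.75 ± 0.92, 1.91 within kind at adjusted p = 0.227) and H3c13† (6.62 ± 0.61, 1.55 within kind at adjusted p = 0.104), and they are uncertain. The largest falls were liver genes C4bp† (-9.99 ± 2.13) and Cyp3a11† (-9.47 ± 1.76), at -8.84 and -8.18 within kind (1 old library), and Wfdc10. This protease inhibitor was at 0 in all 6 old and 4 of 6 young libraries (6.07 ± 13.1 CPM at 6 months, adjusted p = 0.0226). Among the 22 cholesterol synthesis genes, 0 rose, 19 fell and 3 were not called (0 and 20 adjusted over the list alone). Their median was -1.01 (camera adjusted p = 1.76e-06, 0.485 with an estimated correlation). In all, 5289 rose and 5147 fell of 21109. Within library kind, which leaves 1 old female against 3 young, 1081 genes were called, and age and kind cannot be told apart in males. By camera, 112 of 243 list tests were called, 75 higher and 37 lower, and 5 held with an estimated correlation.

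Ageing in nmrHAS2 animals follows. In liver the granule protease Prtn3 of neutrophils rose by 5.59 ± 0.83 (adjusted p = 0.000216, 4.32 within kind), and the eosinophil receptor Ccr3† rose by 7.19 ± 1.87 (adjusted p = 0.0136, 5.4 within kind at adjusted p = 0.316). In kidney the injury receptor Havcr1 rose by 3.9 ± 0.66 (adjusted p = 0.000433) and Grem1, an inhibitor of bone morphogenetic proteins, rose by 4.26 ± 0.37 (adjusted p = 1e-06). In spleen the granzyme Gzmk of T cells rose by 3.93 ± 0.46 (adjusted p = 0.000219) and the collagenase Mmp13 rose by 3.28 ± 0.62 (adjusted p = 0.00405). In muscle Nrep fell by 2.02 ± 0.33 (adjusted p = 0.00493, -1.41 within kind at adjusted p = 0.0876) and the antibody gene Ighg1 rose by 7.71 ± 1.57 (adjusted p = 0.0124, 4.53 within kind at adjusted p = 0.337). In intestine Cyp1a1, an enzyme of foreign compound metabolism, fell by 3.06 ± 0.83 (adjusted p = 0.0366, -5.51 within kind at adjusted p = 0.388). In WAT pancreatic transcripts rose, Try5 (13.92 ± 2.01, -2.98 within kind at adjusted p = 0.899) and Cela2a (13.85 ± 2.16, -4.19 within kind at adjusted p = 0.83), where the 1 old library within kind is the one at 0.303 CPM of pancreatic genes, while the muscle genes Ckm (-8.49 ± 1.2, -6.27 within kind at adjusted p = 0.129) and Xirp2† (-8.05 ± 1.05, -5.8 within kind at adjusted p = 0.0853) fell.

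Fewer genes were called with age in nmrHAS2 than in CreER in each of the 6 tissues. In liver 1914 rose and 1046 fell (2140 calls within kind), in kidney 2124 rose and 2200 fell, and in spleen 1139 rose and 702 fell. In WAT 4147 rose and 3622 fell (1015 within kind), in intestine 908 rose and 284 fell (121), and in muscle 467 rose and 541 fell (76). With library kind as a term the order turned in intestine, 22 in CreER and 72 in nmrHAS2. Leaving out 1 library moved the totals by over 1.5 times: in liver (2960) for old male nmrHAS2 1 (1874), in intestine (1192) for old male nmrHAS2 1 (573), young female nmrHAS2 1, 2 and 3 (665, 730, 601) and young male nmrHAS2 1 and 2 (612, 738), and in spleen (1841) for old female nmrHAS2 1 (1130), old male nmrHAS2 3 (1042), young female nmrHAS2 1 and 2 (973, 924) and young male nmrHAS2 2 (1099). Without the 2 spleen libraries whose transgene level goes against the label it was 916. In muscle (1008) it did so for old female nmrHAS2 1 and 2 (427, 333), old male nmrHAS2 1, 2 and 3 (286, 185, 3161), young female nmrHAS2 1 and 2 (210, 220) and young male nmrHAS2 1, 2 and 3 (434, 331, 309).

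The direct test of whether ageing differs between the genotypes called genes mainly in liver. In nmrHAS2 livers the change with age was more negative than in CreER for Lpl, the lipase that frees fatty acids from lipoproteins, and the macrophage gene Mpeg1: Lpl (-2.54 ± 0.28, adjusted p = 8.72e-05, -2.47 within kind) and Mpeg1 (-2.19 ± 0.25, adjusted p = 8.72e-05, -2.32 within kind). In intestine the smallest p values were those of Gm28635† (6.94 ± 0.7, adjusted p = 0.000228, 11.54 within kind) and Plb1 (-5.81 ± 0.75, adjusted p = 0.00116, -12.41 within kind) and of the defensins Defa20 (-5.17 ± 0.63), Defa21 (-4.7 ± 0.62) and Defa22 (-4.35 ± 0.57), which are uncertain. In all, 2391 rose and 2249 fell in liver (3582 calls within kind), 290 rose and 147 fell in kidney and 264 rose and 69 fell in intestine (9), where rose means a more positive change with age in nmrHAS2. In muscle, spleen and WAT 0 genes passed with edgeR, where 335, 845 and 1287 had an unadjusted p under 0.05 and DESeq2 called 18, 36 and 116. Leaving out 1 library moved the counts by over 1.5 times: in intestine (333) for old female nmrHAS2 1 (897), old male CreER 1 and 2 (218, 188), old male nmrHAS2 1 and 3 (179, 613), young female CreER 1 (195), young female nmrHAS2 1 and 3 (220, 206) and young male CreER 2 (199). In kidney (437) it did so for old female CreER 3 (244), old female nmrHAS2 1, 2 and 3 (206, 670, 246), young female CreER 1 and 2 (202, 180), young female nmrHAS2 1 and 2 (252, 237), young male CreER 2 (261) and young male nmrHAS2 2 (280). From 0, the counts went to other values without spleen libraries old female nmrHAS2 1 and 2 (1, 1), old male CreER 2 (12), old male nmrHAS2 1 (2) and young male CreER 3 (2) and without WAT libraries old female nmrHAS2 3 (3), young female nmrHAS2 2 (4) and young male nmrHAS2 1 and 2 (1, 2).

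The difference of the 24-month genotype change between females and males was tested. In intestine Gsdme, a pore-forming protein of cell death, and the defensins had a more negative change in females: Gsdme (-4.68 ± 0.43, adjusted p = 1.47e-05) and, uncertain for shared reads, Defa20 (-8.99 ± 0.98), Defa22 (-8.28 ± 0.88) and Defa40 (-5.26 ± 0.56), while Gm28635† (13.11 ± 1.15, adjusted p = 1.47e-05) went the other way. In liver Il1rap, a subunit of the interleukin 1 receptor, and the lipase Gpld1 had a more negative change in females, Il1rap (-2.91 ± 0.35, adjusted p = 0.000773) and Gpld1 (-1.53 ± 0.2, adjusted p = 0.000773). The test called 1952 genes as more positive and 1136 as more negative in females in intestine, 125 and 625 in liver, 8 and 13 in spleen, and 92 in all in kidney. In old liver, kidney and spleen all males and no females are of the low kind, so sex and kind cannot be told apart. With only the 24-month libraries fitted it called 123 in intestine, 125 in liver, 1 in kidney and 0 in spleen. In muscle and WAT 0 genes passed with edgeR, where 771 and 741 had an unadjusted p under 0.05 and DESeq2 called 7 and 64. Single libraries changed these counts by over 1.5 times: in intestine (3088) for old female CreER 1 and 2 (1738, 1450), old female nmrHAS2 1 and 2 (5349, 1625), old male CreER 3 (1295) and old male nmrHAS2 3 (1544), and in liver (750) for old female CreER 2 (207), old male CreER 1 and 2 (209, 269) and old male nmrHAS2 1, 2 and 3 (1463, 292, 250). In kidney (92) it did so for old female CreER 1 and 2 (28, 27), old female nmrHAS2 1 and 3 (34, 61), old male CreER 2 and 3 (29, 201) and old male nmrHAS2 1, 2 and 3 (351, 5, 19), and in spleen (21) for old female nmrHAS2 1, 2 and 3 (69, 12, 75), old male CreER 1, 2 and 3 (10, 145, 8) and old male nmrHAS2 3 (47). From 0, muscle went to another count without old female nmrHAS2 1 (1), and WAT without old female CreER 1 (4), old female nmrHAS2 3 (1) and old male CreER 3 (1).

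Within 1 sex, with 3 libraries against 3, females had 5295 calls in intestine (1458 with only the groups compared fitted) and 1359 in liver, and males 1 and 6154, the 1 gene of male intestine being the transgene (7.03 ± 0.85, adjusted p = 0.00157). Left out, single libraries moved these counts by over 1.5 times in females of intestine for old female CreER 1 and 2 (3465, 3240) and of liver for old female CreER 2 and 3 (398, 456) and old female nmrHAS2 2 and 3 (664, 111), and in males of intestine for old male CreER 1 (2) and of liver for old male nmrHAS2 3 (4042).

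The last comparison asks whether the 24-month genotype difference runs against the ageing change of the controls, gene by gene. In liver it did so. The old CreER libraries enter both comparisons with opposite signs, so chance alone gives a negative correlation. A simulation of groups without differences gave a mean r between -0.51 and -0.48 across genes in the 6 tissues, and in liver a central range of -0.78 to -0.06, outside of which the real value lies. In the other 5 tissues it lies within theirs, which decides nothing, since no simulated gene changes with age. The mean r with separate old CreER libraries for the 2 comparisons, over 18 splits, is the value given as split. These splits were all below 0 in liver, intestine (-0.43 to -0.16) and kidney (-0.25 to -0.04), and on both sides of 0 elsewhere. Pearson's r across genes, which are not independent replicates, was -0.86 in liver (covariance -0.848 against -0.0553 simulated, -0.79 split, -0.88 with ageing within kind), -0.51 in intestine (covariance -0.175 against -0.0504 simulated, -0.31 split, -0.55 with ageing within kind) and -0.35 in kidney (covariance -0.055 against -0.0274 simulated, -0.15 split). It was -0.41 in muscle (covariance -0.0955 against -0.0781 simulated, 0.01 split, -0.53 with ageing within kind), -0.45 in spleen (covariance -0.0918 against -0.0531 simulated, -0.14 split) and -0.26 in WAT (covariance -0.121 against -0.0713 simulated, -0.12 split, -0.36 with ageing within kind).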

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

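The tests of library kind in liver and intestine, of single libraries in liver, of depth in WAT and of splits with evenly spread kinds were chosen only after the result was seen.

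The 24-month liver difference between genotypes (6376 genes) is far larger than in the other tissues. Library kind and a single library are argued against: the males, all of 1 kind, gave 6154 genes on their own, and the lowest count with 1 library left out was 5148. Dilution of hepatocyte RNA by other cells is argued against as the whole cause of the Mup rises, since the median log2 change of 20 Mup genes exceeded that of 13 hepatocyte markers by 2.83, but it stays open for other genes, as the markers were higher by 0.36 to 1.07 and the respiration genes by a median of 0.43. Of 30 splits of the old livers the highest other gave 3545 genes, so chance is argued against at that number of splits. A difference between the genotypes in old liver stays open as a hypothesis, found and tested on the same data.

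In intestine the 24-month difference was in females (5295 genes) and the difference between sexes called 3088. Library kind as a term (5306 genes in females) was no test, since both genotypes hold the same kinds. A different stretch of the intestine in the 3 old female CreER samples is a candidate explanation: among genes fixed in advance and not looked at before, the median change of 10 proximal genes minus that of 7 distal genes was 3.02. The distal genes ran from -10.54 to -2.29. Of the proximal ones (median 0.16, -1.97 to 4.1), only Pdx1, Onecut2, Cybrd1 and Slc40a1 were called, all higher (2.98 to 4.1). An effect of genotype in old females stays open, and the 10 splits of 6 libraries are too few for a share under 0.05 (real 5295, highest other 1152).

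In WAT of CreER males 8891 genes were called with age, against 4560 in females. Library kind is a candidate source. Across 17572 genes, which are not independent replicates, the male ageing change followed the difference between kinds inside old male muscle with r = 0.59. That of females gave 0.02. Old male muscle has 1 low-kind library per genotype. That of CreER stood apart, with 5120 CPM of 5 neutrophil genes, so this difference can hold more than kind. Depth is argued against, with a ratio of median total counts of 1.17. Age and kind coincide in these males, so they cannot be told apart, and ageing itself stays open.

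Several tests of a difference between groups passed. Ageing differed between genotypes for 4640 genes in liver, with the smallest p and log2 differences for Lpl -2.54, Mpeg1 -2.19, Hmgb2 -2.01, Itpripl2 -2.06 and Anxa2 -2.03. It differed for 437 genes in kidney, among them Scrn2 0.6, Glrx5 0.5, Ecsit 0.44, Plpp2 0.49 and Tubb4b 0.58. In intestine it differed for 333, among them Gm28635† 6.94, Defa20 -5.17, Plb1 -5.81, Defa21 -4.7 and Defa22 -4.35.

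The 24-month genotype change differed between females and males for 3088 genes in intestine, among them Gsdme -4.68, Gm28635† 13.11, Defa22 -8.28, Defa40 -5.26 and Defa20 -8.99. In liver it differed for 750, among them Il1rap -2.91, Mpzl2 -1.43, Cyp2c68 -1.81, Gpld1 -1.53 and Cyp2c37 -3.89. The 92 genes of kidney include Ccr1 3.95, Grpel2 -0.53, Angptl7 -2.65, Pbld1 -0.84 and Igfals 1.56. In spleen the 21 genes include Ccl24 -6.03, Apobec2 5.54, Fabp5 1.71, Adam22 -1.47 and Avil 9.52.

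Of 30 splits of the same libraries, only the real one called as many genes for the counts that follow. This argues against chance for each count taken alone, at a share under 0.05. The shares were not adjusted over all counts set against splits, so some can rank first by chance. Given with the real value first and the highest other split second, they are for genotype at 24 months 327 and 2 in kidney and 6376 and 3545 in liver. For ageing in CreER 5622 and 1573 in kidney and 2850 and 20 in spleen. For ageing in nmrHAS2 4324 and 74 in kidney and 1841 and 1 in spleen. For the difference in ageing 437 and 24 in kidney and 4640 and 795 in liver. For the difference between sexes 92 and 38 in kidney. With only the 24-month libraries fitted, the 327 and 92 of kidney were 3 and 1. Where kind changes with age, the splits cannot tell age from kind. In CreER these counts are 1775 and 809 in intestine, 3082 and 1598 in muscle and 10436 and 3361 in WAT. In nmrHAS2 they are 1008 and 0 in muscle and 7769 and 4291 in WAT. Kind changes in females alone for liver, with 9540 and 4335 in CreER and 2960 and 8 in nmrHAS2. The splits say nothing of a response to genotype where the calls were the transgene, Has2 that shares its reads and at most 1 other gene: 3 and 1 in muscle at 24 months, and 2 and 1 in muscle and 1 and 0 in spleen at 6 months.

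Chance cannot be excluded at this number of splits, with the number of splits as large in parentheses, for genotype at 24 months 1031 and 2055 in intestine (3 splits), 1 and 793 in spleen (13 splits) and 34 and 1847 in WAT (5 splits). For genotype at 6 months 1202 and 1203 in kidney (2 splits). For ageing in nmrHAS2 1192 and 2998 in intestine (2 splits). For the difference in ageing 333 and 1716 in intestine (2 splits). For the difference between sexes 3088 and 3668 in intestine (2 splits), 750 and 1133 in liver (3 splits), 0 and 1 in muscle (30 splits), 21 and 1350 in spleen (8 splits) and 0 and 1141 in WAT (30 splits). Splits that call several times the real count point to a structure of the samples other than the groups. The highest other split of WAT at 24 months set both many-fraction libraries on 1 side. With kinds spread evenly over the sides, as in the real split, 16 splits of WAT remain with 0 as the highest other, 18 of intestine with 2055 (3 as large), and 17 of liver with 688 for the difference between sexes, each too few for a share under 0.05. Of the gene lists, the number called for genotype ranked first (99, highest other 86). Tissues can come from the same animals, so chance is not excluded. Nor is it for single lists or for ageing in CreER (112, 119, 2 as large).

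Within 1 sex the 10 splits are too few for a share under 0.05. Real value and highest other split were in females 253 and 3 in kidney, 1359 and 8 in liver, 2 and 3 in muscle, 0 and 6 in spleen and 3 and 1921 in WAT, and in males 1 and 3 in intestine, 346 and 300 in kidney, 6154 and 5 in liver, 2 and 990 in muscle, 279 and 3617 in spleen and 0 and 5 in WAT.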

How the results depend on the processing

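Each count, relation and named gene was computed again under the alternatives that apply to it, and gene lists with RLE size factors, a block, an estimated correlation, fry, within kind and in muscle without 1 library. Those listed above as added were chosen after seeing the data. Outside the left-out libraries, 152 values of counts and relations stayed within 1.5 times or 1 spread and 91 moved. Of the named genes' values 6054 kept direction and side of the threshold, 412 no longer passed, 152 newly passed and 15 turned in sign or went to 0. Of the lists' 596 kept their call and 324 lost it, most with an estimated correlation. With fry 22 of 99 of the calls for genotype held (4 of 13 in intestine, 0 of 17 in kidney, 16 of 21 in liver, 0 of 18 in muscle, 1 of 12 in spleen and 1 of 18 in WAT) and 88 of 112 of those for ageing in CreER. With single libraries left out, 12056 values of named genes kept direction and call, 995 lost it and 137 gained it. The planned pseudocount alternative does not apply to counts and was not run. Except where fewer libraries entered a fit, the cause was not tested. Without the library old male CreER 3, 6 of 18 muscle lists held for genotype at 24 months, and 3 turned, with means of 0.87 for neutrophil markers, 0.12 for cell proliferation and 0.02 for cytosolic ribosomal proteins.

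With DESeq2 the count for genotype at 24 months became 1788 in intestine, 930 in kidney, 13 in muscle, 103 in spleen and 114 in WAT. For genotype at 6 months, 2 in intestine, 1869 in kidney, 496 in liver, 46 in muscle, 73 in spleen and 88 in WAT. For ageing in CreER, 2723 in intestine. For ageing in nmrHAS2, 1961 in intestine, 2293 in muscle and 2798 in spleen. For the difference in ageing, 699 in intestine, 1192 in kidney, 18 in muscle, 36 in spleen and 116 in WAT. For the difference between sexes, 483 in kidney, 1260 in liver, 7 in muscle, 320 in spleen and 64 in WAT. Over several tissues it called 458 rises and 354 falls in 2 or more tissues and 23 rises and 25 falls in 3 or more tissues. With fits of only the groups compared the count for genotype at 24 months became 160 in intestine, 3 in kidney, 0 in spleen and 0 in WAT. For genotype at 6 months, 1899 in kidney, 0 in liver and 0 in WAT. For ageing in CreER, 1610 in muscle. For ageing in nmrHAS2, 591 in intestine, 1465 in liver, 1547 in muscle and 1114 in spleen. For the difference between sexes, 123 in intestine, 1 in kidney, 125 in liver and 0 in spleen. Without a filter on low counts the count for genotype at 6 months became 661 in kidney and 37 in liver. For ageing in nmrHAS2, 603 in muscle. For the difference in ageing, 282 in kidney. For the difference between sexes, 484 in liver and 32 in spleen. With RLE size factors the count for genotype at 6 months became 34 in liver. At an adjusted p of 0.01 there were 33 rises and 26 falls in 2 or more tissues and 2 rises and 0 falls in 3 or more tissues.

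With the replicate number as a block the count for genotype at 24 months became 164 in kidney and 3 in spleen. Genotype at 6 months gave 125 in liver, 0 in spleen and 0 in WAT. Ageing in nmrHAS2 gave 2018 in muscle. The difference in ageing gave 207 in intestine and 246 in kidney. The difference between sexes gave 59 in kidney. As a check of pairing, residuals of libraries of equal number correlated above 0.1 in 8 of 12 pairs each in intestine, liver, muscle and spleen, 5 of 12 in kidney and 9 of 12 in WAT.

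With library kind as a term the count for genotype at 6 months became 38 in liver. For ageing in CreER, 22 in intestine and 1608 in muscle. For ageing in nmrHAS2, 72 in intestine. Some genes turned in sign. These were Srp54b 0.04 in intestine with age in CreER, Ccl21d -0.46 in intestine with age in nmrHAS2, Rn7s6 -0.55 and n-R5s193 -0.67 in muscle with age in CreER and n-R5s193 -1.62 in muscle with age in nmrHAS2. Within library kind the count for ageing in CreER became 486 in intestine and 1081 in WAT. Ageing in nmrHAS2 gave 121 in intestine, 76 in muscle and 1015 in WAT. The difference in ageing gave 9 in intestine, 26 in muscle and 1 in WAT. Here genes turned or went to 0, with at most 1 old library per sex in these tissues. There were Srp54b 0.15 in intestine with age in CreER, Ccl21d 0 in intestine with age in nmrHAS2, Rn7s6 -0.4, n-R5s193 -0.64 and Jun -0.01 in muscle with age in CreER, Rn7s6 -0.18 and n-R5s193 -1.92 in muscle with age in nmrHAS2 and Reg2 0, Try5 -2.98 and Cela2a -4.19 in WAT with age in nmrHAS2. The relation r in WAT was -0.36.

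Without WAT libraries with pancreatic transcripts the counts became 7 for genotype at 24 months, 0 for genotype at 6 months, 5068 for ageing in nmrHAS2, 1 for the difference in ageing and 17 for the difference between sexes. Without the 2 spleen libraries whose transgene level goes against the label the counts became 0 for genotype at 24 months and 916 for ageing in nmrHAS2. With separate old CreER libraries for the 2 comparisons the relation r became -0.31 in intestine, -0.15 in kidney, -0.79 in liver, 0.01 in muscle, -0.14 in spleen and -0.12 in WAT. Over genes with a mean of at least 5 CPM it was -0.18 in WAT.

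Counts with 1 library left out at a time follow. For genotype at 24 months, 383 to 2018 in intestine, 29 to 1441 in kidney, 0 to 93 in spleen and 1 to 48 in WAT. For genotype at 6 months, 410 to 1076 in kidney, 0 to 808 in liver, 0 to 6 in spleen and 0 to 35 in WAT. For ageing in CreER, 770 to 2239 in intestine, 1494 to 5728 in muscle and 1777 to 4691 in spleen. For ageing in nmrHAS2, 573 to 1588 in intestine, 1874 to 3933 in liver, 185 to 3161 in muscle and 924 to 2381 in spleen. For the difference in ageing, 179 to 897 in intestine, 180 to 670 in kidney, 0 to 12 in spleen and 0 to 4 in WAT. For the difference between sexes, 1295 to 5349 in intestine, 5 to 351 in kidney, 207 to 1463 in liver, 0 to 1 in muscle, 8 to 145 in spleen and 0 to 4 in WAT. Within 1 sex, the genotype count at 24 months was 253 in female kidney, 22 with only the groups compared fitted and 98 to 428 with 1 library left out. In male kidney it was 346, 27 with a block, 0 with only those groups and 4 to 1425, and in male spleen 279, 2 with only those groups and 37 to 1170.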

Other observations

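In 24-month WAT, brown adipocyte genes were higher as a group. Of the 7 brown adipocyte markers, 0 rose, 0 fell and 7 were not called (2 and 0 adjusted over the list alone). Their median was 0.98 (camera adjusted p = 1.19e-05, 0.661 with an estimated correlation).

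The Mup genes of liver, summed, were at 4030 ± 1310 CPM in old CreER females, 61800 ± 41400 in old nmrHAS2 females, 7650 ± 5780 in old CreER males and 46700 ± 18800 in old nmrHAS2 males (mean ± standard deviation, n = 3). In young CreER they were at 34000 ± 12300 CPM in females and 176000 ± 68000 in males, and in young nmrHAS2 at 31200 ± 7790 and 85700 ± 29100.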
